A study of Mus musculus with 12 samples.

How the data were processed

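RNA sequencing was done on 12 libraries from myofibers of male C57BL/6J mice, in 4 groups of 3 libraries each. The labels give an age of 8 weeks for trained and untrained mice alike. Whether this is the age before or after the 6 weeks of training is not known here. Per the labels, type I myofibers came from the soleus and type IIb myofibers from the extensor digitorum longus, a fast hindlimb muscle. Trained mice ran on a treadmill for 6 weeks, 5 days a week, at 12 to 16 m/min for 60 min, and were killed 3 days after the last run, and untrained mice were the controls. Per the labels' protocols, muscles were digested in collagenase at 2 mg/ml and 37 °C, for 90 min in the case of soleus and 60 min in the case of extensor digitorum longus. Each fibre was divided, and one part was typed by its myosin heavy chain protein while the other was lysed for sequencing. Fibre type, muscle and digestion time therefore changed together and could not be separated. Complementary DNA was made and amplified with the SMART-Seq HT kit, which starts from very small amounts of RNA, and libraries were made with Nextera XT, which does not mark strand.

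The deposited count table holds whole-number read counts per gene, not normalised, with one column for each of the 12 libraries. The deposited FPKM tables hold values scaled to gene length and library total by the authors. Each FPKM value equalled its count divided by the gene length in the table and by the library total, to within 0.1% for 94.5% of nonzero values and with a largest deviation of 0.362%. FPKM values of the per-sample tables equalled those of the series table in all 12 libraries. TopHat2, an aligner of spliced reads, and the mouse genome build mm10 are named per the submitters' processing notes. The version of the aligner, the counting program, the annotation release and the filters are not given in the sources used here. The tables list 56162 features, of which 55401 have Ensembl gene identifiers and 761 are features that the authors list without one. GENCODE M21 (mm10) held 55141 of those identifiers. Symbols shared by more than one identifier numbered 91. Reads from a gene and from an overlapping gene on the other strand cannot be told apart in these counts, and amplified reads carry no molecular identifiers, so intervals and floors cover counting error only. No other per-sample columns were present (0 unused).

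Library totals ranged from 8026397 to 24995288 counts. One count was worth 0.04 to 0.125 CPM, and 3 counts, the floor used for a group at 0, were worth 0.12 to 0.374 CPM in a single library. Samples were grouped by their titles and treatment labels. The labels name no separate animals, so p-values measure only the spread between these samples, which may be partly technical. No library was left out of the main comparisons.

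The tests, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Counts were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (robust fit, TMM normalisation). One fit held all 12 libraries with a mean per group, so that the 4 groups shared one estimate of the spread. Genes passed edgeR's expression filter with a minimum count of 10 and a minimum total count of 15, which left 11747 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold threshold. The 5 comparisons were training within each fibre type, type I minus type IIb in untrained and in trained mice, and the difference between the training effects (interaction). Levels of single genes are CPM with TMM-scaled library sizes, given as mean ± SD of 3 libraries. Summed markers are CPM of the library totals without TMM scaling, so they are not on the scale of single genes. Folds are ratios of counts pooled over a group and divided by the pooled TMM-scaled library sizes, so they can differ from the ratio of mean levels. Against a group without a count the fold is a lower bound from 3 counts over that group, and against a group with 1 to 3 counts a 95% counting interval is given. SE stands for the absolute log2 fold change divided by the square root of the F statistic of edgeR's test. It is not a separately estimated standard error.

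Gene lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of one comparison. Camera compares a list with the other genes, so the direction of a called list is relative to them. Camera with an estimated correlation and limma's fry were run beside it. The 32 lists fixed in advance covered slow and fast contractile genes, fibre type regulators, glycolysis and glycogen, nuclear-encoded oxidative phosphorylation (OXPHOS), mitochondrially encoded genes, the tricarboxylic acid cycle, fatty acid use, mitochondrial regulators, glucose uptake, branched-chain amino acid breakdown, excitation-contraction coupling, immediate early genes, heat shock, endoplasmic reticulum stress, antioxidant defence, atrophy and autophagy, the neuromuscular junction, the circadian clock, myokines, ribosomal proteins, interferon response and extracellular matrix. They also covered markers of endothelial, fibroblast, macrophage, satellite, mural, Schwann, erythroid, adipocyte and tendon cells. Lists with fewer than 3 tested members (macrophage, Schwann and adipocyte markers) were described by summed levels only, which left 29 tested lists. Shares of the myosin heavy chain genes Myh7, Myh2, Myh1 and Myh4 in their summed counts, and numbers of genes detected, were compared with exact two-sided permutation tests of 3 against 3, whose smallest p is 0.1.

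Named genes were, for each comparison, up to 8 called genes per direction with the smallest p whose 3 libraries of one group all lay on one side of the other 3, leaving out unnamed models and genes under 5 CPM in the higher group. In each called list up to 4 called members were added, or the 2 with the smallest p where none was called, and up to 4 members of lists that were not called could be given. Myh7, Myh2, Myh1, Myh4, Ppargc1a and Vegfa were always followed.

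The scripts were tested on simulated data drawn from the real gene means and library sizes, with 200 changed genes. At a 4-fold change, 0, 0, 1, 1 and 1 of 100 changed genes were called for training in type I, training in type IIb, fibre types in untrained mice, fibre types in trained mice and the interaction, and at a 16-fold change 5, 6, 11, 11 and 3 of 100. The simulations tested 10842, 10819, 10937, 10801 and 10847 genes in the same order, with 1, 0, 0, 2 and 2 false calls. Both simulated changed lists were called in each comparison except the interaction, where 0 of 2 were called, and 0, 1, 0, 0 and 0 of 20 unchanged lists were called. Simulated genes were drawn independently of each other. In the data the estimated correlation with training in type I was 0.376 for OXPHOS and 0.787 for mitochondrially encoded genes. The simulation therefore does not show how often camera calls unchanged lists in these data. Changes of up to 16-fold in single genes were therefore mostly missed with these libraries.

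Alternatives were DESeq2 size factors (RLE) in place of TMM, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, edgeR without a robust prior, no filter on low counts, a stricter filter, an added log2 fold threshold of 1, a fit of only the groups compared, the replicate number as a block, limma on log2(FPKM + 1) and log2(FPKM + 0.1), and leaving out each library in turn. Leaving out the 3 libraries with the highest endothelial markers, and the 2 libraries with the fewest detected genes, were chosen after seeing the data. The first 3 were type I untrained libraries 1 and 3 and type IIb trained library 3, with 11703, 14428 and 10932 genes of at least 10 counts. Each had more genes than the remaining libraries of its group, so leaving them out also changes the number of genes detected. RLE in place of TMM moved the median log2 fold change of all genes from -0.28 to -0.57 for training in type I, from 0.36 to 0.38 for training in type IIb, from 0.85 to 1.17 between fibre types in untrained mice, from 0.21 to 0.17 between fibre types in trained mice and from -0.68 to -1.01 for the interaction.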

Results

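Gene expression was measured by RNA sequencing in type I myofibers, the slow oxidative fibres taken here from soleus, and in type IIb myofibers, the fast glycolytic fibres taken here from extensor digitorum longus. Mice were untrained or trained by treadmill running, and each of the 4 groups had 3 libraries. Library totals were 11726789 to 24995288 counts in type I untrained, 9692597 to 13919488 in type I trained, 9707337 to 14408531 in type IIb untrained and 8026397 to 15292039 in type IIb trained libraries. Genes with at least 10 counts numbered 11947 ± 2368 (SD, n = 3) in type I untrained, 8150.3 ± 3213 in type I trained, 6269 ± 2777 in type IIb untrained and 7044 ± 3463 in type IIb trained libraries. The trained minus untrained difference was -3797 genes in type I, larger than either SD, and 775 genes in type IIb fibres, smaller than either SD. An exact two-sided permutation test of 3 against 3, which cannot give p below 0.1, gave p = 0.3 and p = 0.7. Mitochondrially encoded genes took 17.6 ± 3.7%, 19.9 ± 14.4%, 27.8 ± 0.9% and 26.3 ± 2.6% of the counts in the same order, with type I trained libraries between 5.86% and 34.7%. Libraries of one group correlated with Pearson r between 0.58 and 0.77 across genes. The first principal component held 36.7% of the variance. Over the 12 libraries it followed log10 of the number of genes detected with Pearson r = -0.982 and Spearman rho = -0.979 (permutation p = 1e-05 for each, the smallest the permutations could give). Without the 2 libraries farthest from the median r was -0.973, and within fibre types r was -0.983 in type I and -0.996 in type IIb.

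**Figure D1:**
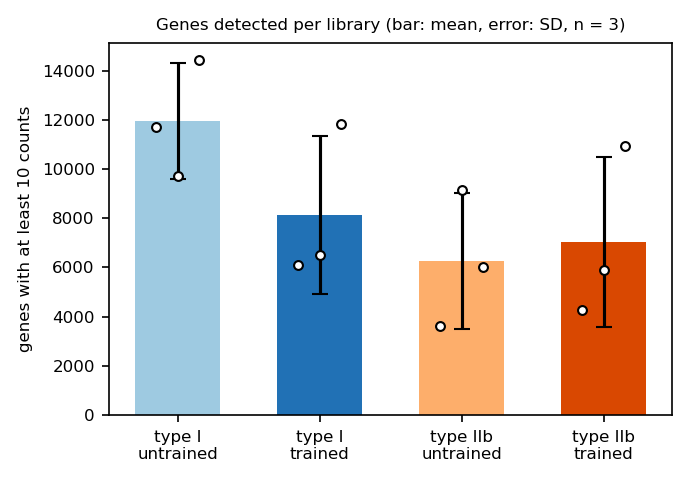
Number of genes with at least 10 counts (vertical axis) in the 4 groups (horizontal axis), with bars for the mean, error bars for the SD and points for the 3 libraries of each group. The means were 11947, 8150.3, 6269 and 7044 genes in type I untrained, type I trained, type IIb untrained and type IIb trained libraries.

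The myosin heavy chain genes showed the fibre type of every library. Myh7, the slow heavy chain of type I fibres, made up 92.1 ± 10.1% (SD, n = 3) of the counts of Myh7, Myh2, Myh1 and Myh4 in type I untrained and 97.0 ± 4.77% in type I trained libraries. Myh4, the heavy chain of type IIb fibres, made up 99.9% on average in both type IIb groups. In type I fibres Myh2, the heavy chain of type IIa fibres, held 10.5%, 0.863% and 2.34% of these counts in the untrained and 0, 0 and 0.126% in the trained libraries. This is a full separation with p = 0.1, the smallest that an exact two-sided permutation test of 3 against 3 can give. Type I shares of Myh7, Myh1 and Myh4 had p = 0.5, 0.5 and 0.2 in the same exact test. Myh7 (ENSMUSG00000053093, mm10 chromosome 14, 54970684 to 54994626) had 1399 to 13440 counts per type I library and 1 count in all type IIb libraries together. Its mean level in untrained type I fibres, 387 ± 146 CPM (counts scaled to library size), lay below that of Myh4 (ENSMUSG00000057003, chromosome 11, 67238029 to 67260446) in untrained type IIb fibres, 37327 ± 15907 CPM. Exon sequence that Myh7 shares with overlapping genes came to 13.3% of its length. The 4 genes together had 1529 to 13487 counts per type I library, most of them of Myh7. The type I shares therefore depend on the low counts of Myh7, whose cause stays open.

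In untrained mice, type I and type IIb fibres differed in slow and fast contractile genes. Genes of the slow sarcomere were higher in type I fibres, among them Myh7, Myl2 (slow regulatory light chain), Myoz2 and Csrp3 (Z-disc proteins), Ankrd2 (a stretch-responsive ankyrin-repeat protein) and Sln (sarcolipin, a regulator of the calcium pump). Type IIb fibres had higher levels of fast partners, among them Mylpf (fast regulatory light chain), Mybpc2 (fast myosin-binding protein C), Casq1 (calsequestrin, which stores calcium) and the glycolytic enzymes Ldha and Aldoa. Tspan8, a tetraspanin membrane protein, was also higher in type IIb fibres. Idh2, the mitochondrial isocitrate dehydrogenase, and Cryab, a small heat shock protein of the sarcomere, were higher in type I fibres. Of 11747 genes, 30 were higher and 24 lower in type I than in type IIb fibres at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 2053 genes (1825 higher, 228 lower), where 587 would be expected by chance. The median log2 fold change of all genes was 0.85. More genes were also detected in untrained type I than in untrained type IIb libraries (11947 and 6269 on average). Whether this adds to the excess of higher genes was not tested. All 54 called genes had 3 libraries of one group above the 3 of the other, as did 3251 genes in all (27.7%, where chance gives 10% for 3 against 3). DESeq2 called 1028 higher and 53 lower and limma-voom with quality weights 1868 and 238.

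Mylpf (ENSMUSG00000030672, chromosome 7, 127208890 to 127214298) averaged 28832 ± 7950.1 CPM (SD, n = 3) in type IIb and 482 ± 180.5 CPM in type I fibres, a 64.2-fold difference (log2 fold change of type I over type IIb -5.90 ± 0.45 SE, adjusted p = 9.75e-07, edgeR quasi-likelihood test). Myl2 (ENSMUSG00000013936, chromosome 5, 122100951 to 122113472) averaged 7550.2 ± 3641 CPM in type I fibres and had 19 counts in all type IIb untrained libraries (11470-fold, adjusted p = 1.16e-06, edgeR). Myh7 had no count in these type IIb libraries and was at least 3670-fold higher in type I fibres (adjusted p = 8.53e-06, edgeR). Ankrd2 (ENSMUSG00000025172, chromosome 19, 42036000 to 42045110) averaged 861 ± 270.1 CPM against 1 count, a ratio of 27080 with a counting interval from 4860 to 1070000 (adjusted p = 1.16e-06, edgeR). Tspan8 (ENSMUSG00000034127, chromosome 10, 115816832 to 115849893) averaged 389 ± 149.6 CPM in type IIb fibres and had no count in type I fibres, at least 8781-fold lower (adjusted p = 1.45e-05, edgeR). Idh2 (ENSMUSG00000030541, chromosome 7, 80094846 to 80115392) averaged 1209.8 ± 342 CPM in type I and 28.9 ± 11.5 CPM in type IIb fibres (37.1-fold, log2 fold change 5.38 ± 0.54 SE, adjusted p = 9.32e-06, edgeR). Also called were Mylf-ps, a pseudogene of a fast light chain whose reads can be shared with Myl1 (47.1-fold lower in type I), Sar1b, a GTPase of vesicle transport (14.7-fold lower), Casq1 (9.59-fold lower) and Cryab (4.61-fold higher). Further calls were Rrad, Myoz2, Csrp3 and Sln (higher), and Mybpc2, Myh4 and Mstn, which encodes the growth inhibitor myostatin (lower), with at most 5 counts in the lower fibre type for each except Myh4, which had 23.

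**Figure D2:**
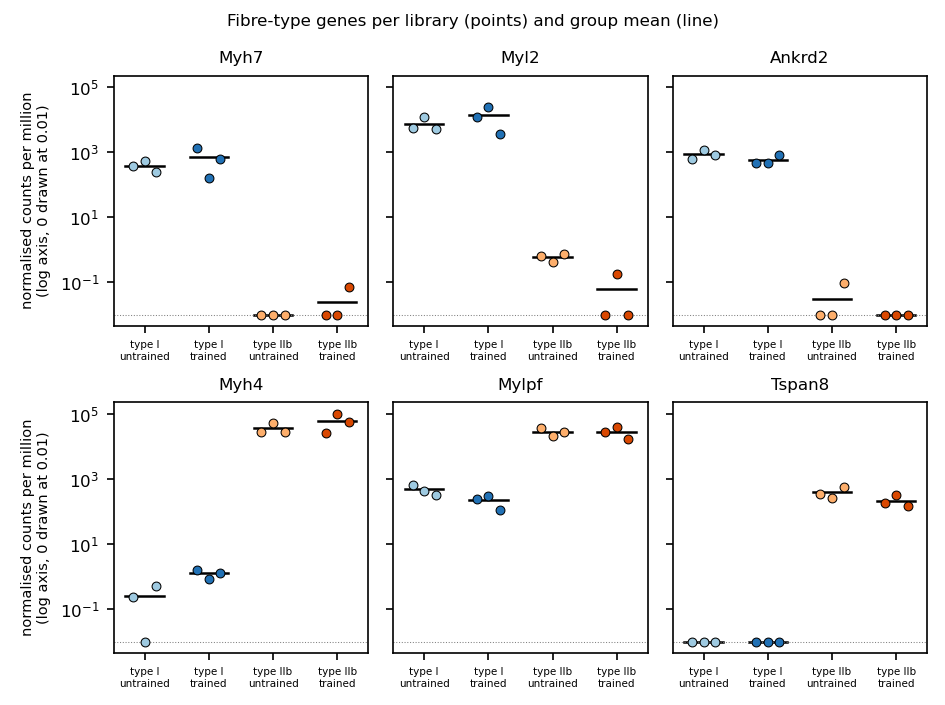
Levels of Myh7, Myl2, Ankrd2, Myh4, Mylpf and Tspan8 in CPM (log axis, with 0 drawn at 0.01) in the 4 groups, with a point per library and a line at the mean of 3. Myl2 averaged 7550.2 CPM in untrained type I fibres and Mylpf 28832 CPM in untrained type IIb fibres.

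Of the gene lists, slow contractile genes were higher in untrained type I fibres (camera adjusted p = 1.46e-58, and 4.39e-05 with an estimated correlation), with 13 of 15 members called and 15 when adjusted over the list alone. Fast contractile genes were lower (camera adjusted p = 7.63e-62, and 0.000304 with an estimated correlation), with 9 of 14 called and 12 adjusted over the list alone. In the fast list Tnnc2, the fast troponin C (ENSMUSG00000017300, chromosome 2, 164777161 to 164779967), averaged only 0.0844 CPM in untrained type IIb fibres and was below the filter. Of its exon sequence 74.0% lies over another gene. Glycolysis and glycogen genes were lower in type I fibres (camera adjusted p = 3.08e-18, median log2 fold change -2.02), with 5 of 20 called and 13 adjusted over the list alone, a list call lost at adjusted p = 0.0708 with an estimated correlation. Ldha, Aldoa, Pgam2 and Eno3, all glycolytic enzymes, were 10.6-fold, 5.07-fold, 5.51-fold and 14.8-fold lower. Mitochondrially encoded genes were lower in type I fibres in 13 of 13 cases (median -1.73, camera adjusted p = 1.10e-13, 3 lower adjusted over the list alone). Nuclear OXPHOS genes were lower in 56 of 76 (median -0.30, adjusted p = 2.33e-12) and ribosomal protein genes in 35 of 54 (median -0.21, adjusted p = 4.31e-08). With an estimated correlation these had adjusted p = 0.238, 0.359 and 0.433. Genes of excitation-contraction coupling, glucose uptake and fibre type regulation were also lower as lists (camera adjusted p = 9.13e-05, 0.000369 and 0.00219). With an estimated correlation these had adjusted p = 0.238, 0.257 and 0.336. Adjusted over the list alone, 2 coupling genes and 4 glucose uptake genes were lower, and of the regulators 1 was higher and 2 were lower. Ppp1r3a, a glycogen phosphatase subunit, was the 1 glucose uptake gene called over all genes. Trdn (triadin, at the calcium release channel) averaged 3713 ± 381 CPM in type IIb and 1068 ± 325 CPM in type I fibres. The transcription factor genes Maf and Prox1 averaged 491 against 19.0 CPM and 0 against 47.1 CPM. None of the 3 was called (adjusted p = 0.156, 0.115 and 0.182, edgeR). Tricarboxylic acid cycle genes were called lower at camera adjusted p = 0.0312 with a median of -0.12 but a mean of 0.15, and at adjusted p = 0.626 with an estimated correlation. Its member Idh2 was higher.

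Fatty acid genes were higher in type I fibres in 24 of 26 cases (median 1.48, camera adjusted p = 0.0118, adjusted p = 0.569 with an estimated correlation, 1 member called adjusted over the list alone). Fabp3, the muscle fatty acid binding protein, averaged 1110.1 ± 358 CPM against 97.0 ± 83.5 CPM without passing over all genes (adjusted p = 0.0896, edgeR). Lists of endothelial, mural and fibroblast markers, extracellular matrix, myokines and interferon response were higher in type I fibres, with camera adjusted p = 0.000163, 0.00219, 0.00276, 0.00561, 0.0118 and 0.0155. With an estimated correlation they had adjusted p = 0.433, 0.359, 0.463, 0.572, 0.359 and 0.433. Adjusted over the list alone, 13 endothelial, 8 mural, 9 fibroblast, 14 matrix, 4 myokine and 0 interferon members were higher. Over all genes Sparc, a matrix protein counted among the myokines, was the 1 called member. Levels of these markers differed widely between single libraries. Summed endothelial markers were 67.3 to 1871 CPM in type I untrained libraries and 0 in type IIb untrained libraries. Summed fibroblast markers were 34.5 to 9814 CPM against 7.46 ± 3.91 CPM, and summed erythroid markers reached 1616 CPM in 1 type I untrained library. The other 12 lists, on mitochondrial regulators, branched-chain amino acid breakdown, immediate early genes, heat shock, endoplasmic reticulum stress, antioxidant defence, atrophy and autophagy, the neuromuscular junction, the circadian clock, satellite cells, erythroid cells and tendon cells, had camera adjusted p between 0.0851 and 0.849. Leaving out single libraries gave 14 to 39 higher and 8 to 30 lower genes, with 19, 18, 14 and 16 higher genes without type I untrained library 1, 2 or 3 or type IIb untrained library 3, and 14, 11, 8, 15 and 11 lower genes without type I untrained library 1, 2 or 3 or type IIb untrained library 2 or 3. It ended the calls of Ldha (without type I untrained library 3), Aldoa (also without type IIb untrained library 2), Pgam2 (4 of the leave-outs), Mstn (5), Ppp1r3a (6), Eno3 (8) and Sparc (8), with adjusted p up to 0.0601, 0.0734, 0.129, 0.161, 0.366, 0.366 and 0.405 in edgeR. Without type IIb untrained library 2 the fibroblast, mural, matrix, myokine, fatty acid and tricarboxylic acid cycle lists were not called (camera adjusted p = 0.0603, 0.0901, 0.0901, 0.0648, 0.0562 and 0.0562). The fatty acid list was also lost without type I untrained library 2 (0.277), and the tricarboxylic acid cycle and matrix lists without type I untrained library 3 (0.126 and 0.0709).

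Limma-voom with quality weights did not call Mylpf, Myl2, Sln, Csrp3, Myh4, Cryab and Sparc in untrained mice, and DESeq2 did not call Cryab, Ldha, Aldoa, Pgam2, Eno3 and Ppp1r3a. EdgeR without a robust prior lost Aldoa, Pgam2, Sparc, Eno3 and Ppp1r3a (adjusted p = 0.0693 to 0.143), and the fit of only the groups compared lost Cryab, Mstn, Pgam2, Sparc, Eno3 and Ppp1r3a (0.0540 to 0.107). RLE size factors lost Sparc and Eno3 (0.0928 and 0.0725), and Ppp1r3a was also lost without a filter and on both FPKM scales (0.145 to 0.394). A fit without the 3 libraries with the highest endothelial markers (the marker libraries) was chosen after seeing the data. It leaves 1 untrained type I library, assumed to vary like the other groups. In this fit Myl2, Csrp3, Casq1, Mylf-ps, Ldha and Aldoa were not called by edgeR. Mstn, Pgam2, Eno3, Ppp1r3a and Sparc were lost as well, and the log2 fold change of Sparc fell from 7.45 to 2.19. The endothelial, fibroblast, matrix and interferon lists (camera adjusted p = 0.0526, 0.349, 0.578 and 0.462) and those of ribosomal proteins, fibre type regulators and the tricarboxylic acid cycle (0.349, 0.214 and 0.483) were then not called either. Without the 2 libraries with the fewest genes, also chosen after seeing the data, Aldoa, Pgam2, Sparc and Eno3 were not called (edgeR adjusted p = 0.0914 to 0.121). Of the 12 lists that were not called, 3 were called higher in single leave-outs: heat shock without type IIb untrained library 1 or 3 (camera adjusted p = 0.0420 and 0.0452), immediate early genes without type IIb untrained library 3 (0.00941) and erythroid markers without type I untrained library 3 (0.0126). Heat shock and immediate early genes were also called without the 2 libraries with the fewest genes (0.0405 and 0.0416) and without a filter (0.0110 and 0.00237).

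Trained type I and type IIb fibres also differed in slow and fast contractile genes. Myl2, Ankrd2, Myoz2, Myh7 and Sln were again higher in type I fibres, with Myom3, a component of the sarcomeric M band, and Vgll2, a transcription cofactor. Mylpf, Mybpc2, Myh4 and Tspan8 were again lower, with Atp2a1 (the fast calcium pump), Myoz1 (a Z-disc protein of fast fibres), Slc16a3 (a lactate exporter), Gapdh (a glycolytic enzyme) and Gpx3 (a secreted glutathione peroxidase). Of 11747 genes, 28 were higher and 35 lower in type I fibres in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. An unadjusted p under 0.05 was reached by 943 (596 higher, 347 lower). All 63 called genes separated the libraries, as did 1232 genes in all (10.5%). DESeq2 called 171 higher and 113 lower and limma-voom with quality weights 126 and 50. The calls of trained and untrained mice shared 26 higher and 21 lower genes, where independent lists would share 0.0715 in each direction (two-sided Fisher's exact test, p = 6.52e-73 and p = 8.28e-54). Across all genes the fibre differences correlated with Pearson r = 0.263 and Spearman rho = 0.205, across genes that are not independent replicates.

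Mylpf was 138.7-fold lower in trained type I fibres (log2 fold change -7.02 ± 0.48 SE, adjusted p = 1.21e-07, edgeR quasi-likelihood test). Myl2 averaged 13845 ± 10931 CPM against 1 count in all type IIb trained libraries (ratio 276600, counting interval 49640 to 10920000, adjusted p = 2.17e-07, edgeR), and Myh7 694 ± 583 CPM against 1 count (ratio 17670, interval 3172 to 698100, adjusted p = 9.38e-06). Ankrd2, Myom3 and Tspan8 had no count in the lower fibre type, which made Ankrd2 and Myom3 at least 5971-fold and 2898-fold higher and Tspan8 at least 2543-fold lower in type I fibres. Idh2 averaged 1396 ± 357 CPM in type I and 111 ± 17.5 CPM in type IIb fibres (11.3-fold, adjusted p = 0.000416, edgeR). Cryab was 8.76-fold higher and Casq1, Atp2a1 and Myoz1 were 12.7-fold, 66.2-fold and 89.5-fold lower in type I fibres, with adjusted p between 0.000119 and 0.00146 in edgeR. Gpx3 averaged 297 ± 28.1 CPM in type IIb and 1.99 ± 3.03 CPM in type I fibres (adjusted p = 0.0210, edgeR).

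Slow contractile genes were higher as a list (camera adjusted p = 3.48e-82, and 3.87e-06 with an estimated correlation), with 12 of 15 called and 14 adjusted over the list alone. Fast contractile genes were lower (camera adjusted p = 9.35e-67, and 0.000341 with an estimated correlation), with 10 of 14 called and 13 adjusted over the list alone. Glycolysis and glycogen genes were lower with 8 of 20 called and 15 adjusted over the list alone (median log2 fold change -2.76, camera adjusted p = 1.65e-19, adjusted p = 0.0652 with an estimated correlation). Aldoa, Ldha, Gapdh and Pgam2 were 11.7-fold, 15.7-fold, 9.56-fold and 7.58-fold lower. Heat shock genes were higher in 15 of 16 cases (median 1.97, camera adjusted p = 9.27e-07, adjusted p = 0.0694 with an estimated correlation), with Cryab called and 7 members adjusted over the list alone. Fatty acid genes were higher in 22 of 26 cases (median 1.72, camera adjusted p = 2.49e-07, adjusted p = 0.409 with an estimated correlation, 2 adjusted over the list alone). Fabp3 averaged 1532 ± 907 CPM against 130.4 ± 101 CPM (adjusted p = 0.0806, edgeR, not called). Erythroid markers were higher in 4 of 4 cases at camera adjusted p = 0.0327 and adjusted p = 0.543 with an estimated correlation. Their sums were 66.9 ± 22.9 CPM in type I and 17.5 ± 30.3 CPM in type IIb trained fibres. Lower as lists were excitation-contraction coupling (15 of 16, median -1.05, camera adjusted p = 1.81e-05), mitochondrially encoded genes (13 of 13, median -0.56, 0.000471), glucose uptake (0.00624) and fibre type regulators (0.0499). With an estimated correlation these 4 had adjusted p = 0.191, 0.545, 0.457 and 0.543. Adjusted over the list alone, 2 coupling and 4 glucose uptake genes were lower. Called over all genes were Slc16a3 and Prkab2, a subunit of AMP-activated kinase, in the glucose uptake list, and Vgll2 (higher) and Tbx15, a T-box factor of glycolytic fibres (lower), among the regulators. The other 19 lists, among them OXPHOS, ribosomal proteins, the tricarboxylic acid cycle, endothelial, fibroblast, mural and tendon markers, had camera adjusted p between 0.108 and 0.998. Leaving out single libraries gave 13 to 40 higher and 16 to 37 lower genes, with 17, 18, 17, 18 and 13 higher genes without type I untrained library 1 or 3, type I trained library 1 or 2 or type IIb trained library 2, and 19 and 16 lower genes without type I trained library 1 or type IIb trained library 2. It ended the calls of Gpx3 and Mstn (3 leave-outs each), Prkab2 (4), Vgll2 (7) and Tbx15 (9), with adjusted p up to 0.0971, 0.112, 0.147, 0.256 and 0.268 in edgeR. The mitochondrially encoded and glucose uptake lists were not called without type I trained library 3 (camera adjusted p = 0.773 and 0.106) or type IIb trained library 1 (0.0600 and 0.0541), and the lists of fibre type regulators and erythroid markers were not called in 9 and 4 of the leave-outs (up to 0.389 and 0.125). None of these 4 lists was called without the 2 libraries with the fewest genes. Limma-voom with quality weights did not call Mylpf, Myl2, Myoz2, Sln, Csrp3, Cryab, Myh4, Aldoa, Idh2, Myoz1, Vgll2 and Tbx15, and DESeq2 did not call Gapdh, Pgam2, Prkab2 and Tbx15. The fit of only the groups compared lost Aldoa, Gapdh, Pgam2, Gpx3, Prkab2 and Tbx15 (adjusted p = 0.0541 to 0.217), and edgeR without a robust prior and without a filter lost Prkab2, Vgll2 and Tbx15 (0.0647 to 0.143 and 0.137 to 0.590). Prkab2 and Tbx15 were also lost on both FPKM scales (0.0698 to 0.0947), and Tbx15 with RLE size factors and without the 2 libraries with the fewest genes (0.0580 and 0.0911). Without the 3 marker libraries Myl2, Csrp3, Vgll2 and Tbx15 were not called (0.0576, 0.0906, 0.232 and 0.0642).

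Of the 19 lists that were not called in trained mice, some were called under other choices of libraries. Ribosomal proteins were called lower without the 3 marker libraries (camera adjusted p = 0.0153) or type IIb trained library 3 (0.0143). They were called higher without the 2 libraries with the fewest genes (0.00357), type I trained library 3 (0.00523) or type IIb trained library 1 (0.00661), so their direction was not settled. OXPHOS was called higher without the 2 libraries with the fewest genes (0.0371) or type I trained library 3 (0.000854), and antioxidant defence without those 2 libraries (0.00933) or type IIb trained library 1 (0.0237). Endothelial markers were called lower without those 2 libraries (0.0371), type I trained library 2 (0.00344) or type IIb trained library 1 or 2 (0.0308 and 0.00576), and without a filter (0.0312). Extracellular matrix was called higher without the 3 marker libraries (0.0151) and immediate early genes without type I trained library 3 (0.0333).

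For endurance training of type I fibres, a question named in the series title, no single gene passed the test. As lists, ribosomal protein genes and genes of mitochondrial energy production, both nuclear OXPHOS and mitochondrially encoded, were higher in trained type I fibres. Markers of endothelial, fibroblast and mural cells, extracellular matrix genes and immediate early genes, which are induced within minutes of a stimulus, were lower. Each of these list calls was lost when the correlation between genes was estimated. Other splits of the same libraries into 3 and 3 gave a median of 10 called lists, against the 13 called here. Of 11747 genes, 0 were called in either direction by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (smallest adjusted p = 0.990). At an unadjusted p under 0.05 there were 345 genes (48 higher, 297 lower). DESeq2 called 1 higher and 46 lower, limma-voom with quality weights 1 and 3, and limma on log2(FPKM + 1) 0. Genes with full separation of the libraries came to 1376 (11.7%).

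Ribosomal protein genes had positive fold changes in 54 of 54 cases (median log2 fold change 0.68, camera adjusted p = 1.44e-15). Rpl30 and Rpl4 averaged 147 ± 99.4 and 476 ± 247 CPM in untrained and 470.3 ± 242 and 1060.4 ± 618 CPM in trained type I fibres. Nuclear OXPHOS genes were positive in 56 of 76 cases (median 0.45, camera adjusted p = 2.28e-10). Cox7c, a subunit of cytochrome c oxidase (ENSMUSG00000017778, chromosome 13, 86044816 to 86046904), averaged 2519.8 ± 1348 CPM in untrained and 7235 ± 4012 CPM in trained type I fibres (log2 fold change 1.52 ± 0.54 SE) and was not called. Ndufa4 averaged 1311 ± 436 and 2554 ± 984 CPM. Mitochondrially encoded genes were positive in 13 of 13 cases (median 1.13, camera adjusted p = 4.37e-06), with mt-Atp6, a subunit of ATP synthase, at 202 ± 61.1 and 619 ± 517 CPM. As a share of unscaled counts, mitochondrial genes took 17.6 ± 3.7% in untrained and 19.9 ± 14.4% in trained libraries (exact permutation p = 0.8). TMM factors were 1.432, 1.063 and 1.54 in untrained and 0.832, 0.84 and 1.62 in trained libraries, so these fold changes also depend on the scaling. Lists of the tricarboxylic acid cycle (17 of 23 positive), fatty acid use (21 of 26; median 0.69, mean 0.13), heat shock (14 of 16) and branched-chain amino acid breakdown (10 of 15) were higher with camera adjusted p = 0.000442, 0.00322, 0.00322 and 0.0458. Dld, of the tricarboxylic acid cycle list, averaged 175 ± 27.2 and 471 ± 368 CPM and the chaperonin gene Hspe1 221 ± 122 and 463 ± 138 CPM, neither called. All 7 higher lists had adjusted p = 0.519 with an estimated correlation.

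Immediate early genes were negative in 18 of 20 cases (median -1.60, camera adjusted p = 0.00322). Egr1, a zinc finger factor of this group (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984), averaged 1305 ± 587 CPM in untrained and 395 ± 279 CPM in trained type I fibres, and Fosb averaged 154 ± 211 and 4.01 ± 4.92 CPM. Endothelial markers were negative in 13 of 13 cases (camera adjusted p = 9.77e-06), fibroblast markers in 11 of 11 (0.00322), extracellular matrix in 19 of 20 (0.00322), mural markers in 7 of 8 (0.0112) and interferon response in 12 of 13 (0.0299). These 6 lists had adjusted p = 0.519 with an estimated correlation, or 0.655 for extracellular matrix. Cdh5, the cadherin of endothelial cells (ENSMUSG00000031871, chromosome 8, 104101625 to 104144511), averaged 51.2 ± 50.7 CPM in untrained fibres and had 1 count in the trained libraries (ratio 2056, counting interval 369 to 81210). Fn1, the matrix protein fibronectin, averaged 278 ± 481 and 0.679 ± 0.920 CPM, and Rgs5, a pericyte marker, 187 ± 147 and 0.196 ± 0.340 CPM. These markers were uneven between libraries of one group. Summed endothelial markers averaged 964 ± 902 CPM in untrained (67.3 to 1871) and 81.1 ± 127 CPM in trained type I libraries (1.96 to 228). Summed tendon markers averaged 1757 ± 2932 and 24.9 ± 29.6 CPM (higher in the untrained library in 9 of 9 pairs, exact two-sided permutation p = 0.1). Of the 9 tendon markers 3, 4 and 9 had any count in the untrained and 4, 5 and 4 in the trained libraries. Erythroid sums were 547 ± 926 and 66.9 ± 22.9 CPM, macrophage sums 63.8 ± 92.7 and 21.9 ± 36.9 CPM, adipocyte sums 118 ± 31.1 and 88.2 ± 72.9 CPM and Schwann cell sums 21.8 and 3.46 CPM.

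The other 16 lists in type I fibres, among them slow and fast contractile genes, glycolysis, glucose uptake, mitochondrial regulators and tendon cells, had camera adjusted p between 0.0934 and 0.782. Adjusted over the list alone, 1 mural marker, 1 glucose uptake gene (Slc16a3) and 1 myokine (Sparc) were lower, and 0 members of the remaining 26 lists passed. Myh7 averaged 387 ± 146 and 694 ± 583 CPM, and Ppargc1a, the coactivator of mitochondrial biogenesis, and Vegfa, the vascular growth factor, averaged 59.2 against 59.6 and 231 against 162 CPM (adjusted p = 1 for each, edgeR). Without type I trained library 3 the endothelial, fibroblast, matrix, mural and immediate early lists were not called (camera adjusted p = 0.0719 for endothelial and 0.250 for immediate early genes). The interferon list was lost there too (0.152) and without type I untrained library 1 (0.0839). The fibroblast, matrix, mural and interferon lists were also lost without type I untrained library 3 (0.712, 0.712, 0.292 and 0.225), the tricarboxylic acid cycle, fatty acid and heat shock lists without type I trained library 1 (0.0615, 0.595 and 0.164) and the mitochondrially encoded list without type I trained library 2 (0.473). The list of branched-chain amino acid breakdown was lost without type I untrained library 3 (0.285) and without type I trained library 2 (0.547). Of the 16 lists that were not called, 5 were called in single leave-outs. Mitochondrial regulators and slow contractile genes were higher without type I untrained library 2 (0.0236 and 0.0187), mitochondrial and fibre type regulators without type I trained library 2 (0.0226 and 0.0490) and erythroid markers without type I untrained library 1 (0.000635). Fast contractile genes were lower without type I untrained library 3 or type I trained library 2 (0.0429 and 0.0442), and tendon markers were lower without a filter (0.0144).

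Without the 3 marker libraries 0 lists were called for training in type I fibres, where 1 untrained library was left and was assumed to vary like the other groups. The median log2 fold changes of OXPHOS and ribosomal proteins were then -0.018 and 0.055 (0.45 and 0.68 with all libraries, camera adjusted p = 0.974 for both). Mitochondrially encoded and immediate early genes had 0.82 and -1.15 (1.13 and -1.60 with all libraries, camera adjusted p = 0.561 and 0.399), while the median of all genes moved from -0.28 to 0.30.

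**Figure D3:**
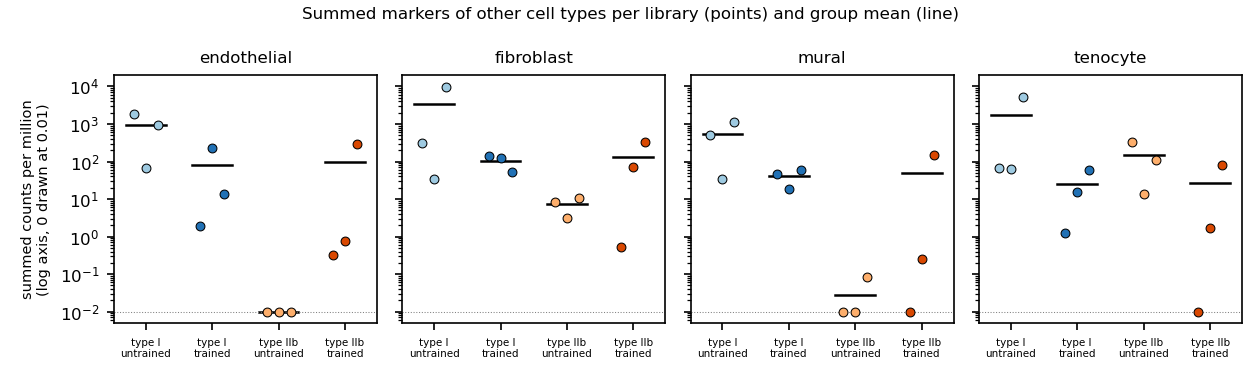
Summed CPM, without TMM scaling, of endothelial, fibroblast, mural and tendon cell markers (log axis, with 0 drawn at 0.01). The 4 groups are shown with a point per library and a line at the mean of 3. Endothelial sums reached 1871 CPM in a type I untrained library and were 0 in all type IIb untrained libraries.

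No single gene passed the test for training in type IIb fibres either. As lists, nuclear OXPHOS genes were lower and endothelial and fibroblast markers higher in trained type IIb fibres, and each list call was lost with an estimated correlation (adjusted p = 0.940 for all 3). Other splits of the same libraries into 3 and 3 gave a median of 4 called lists, against the 3 called here. Of 11747 genes, 0 were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (smallest adjusted p = 0.597), with 965 at an unadjusted p under 0.05 (807 higher, 158 lower). DESeq2 called 277 higher and 46 lower, limma-voom with quality weights 1 and 0, and limma on log2(FPKM + 1) 0. Genes with full separation came to 556 (4.7%).

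Nuclear OXPHOS genes were negative in 52 of 76 cases (median log2 fold change -0.32, camera adjusted p = 0.000196). Ndufb10, a subunit of complex I, averaged 1018 ± 52.4 CPM in untrained and 433 ± 359 CPM in trained type IIb fibres, and Atp5j, a subunit of ATP synthase, 2869 ± 897 and 1491 ± 616 CPM. Endothelial markers were positive in 13 of 13 cases (camera adjusted p = 0.00146) and fibroblast markers in 11 of 11 (0.00346). Cdh5 had no count in untrained and averaged 8.71 ± 14.5 CPM in trained libraries (at least 142-fold), and Lum, a collagen-binding proteoglycan, and Ly6c1 were at least 135-fold and 151-fold higher in pooled counts. Of the summed endothelial markers of the trained libraries, 290.7 CPM were in library 3 and 1.06 CPM in both others together, and without library 3 the OXPHOS, endothelial and fibroblast lists were not called (camera adjusted p = 0.0642, 0.411 and 0.201). The endothelial and fibroblast lists were also lost without type IIb untrained library 2 (0.140 and 0.124). OXPHOS was still called lower without the 3 marker libraries, to which library 3 of the trained fibres belongs. Without the 2 libraries with the fewest genes all 3 lists stayed called (camera adjusted p = 5.27e-05 for OXPHOS, 3.18e-05 for endothelial and 9.15e-06 for fibroblast markers). Macrophage sums were 47.5 CPM in untrained and 0.561 CPM in trained fibres (higher in the untrained library in 9 of 9 pairs, exact two-sided permutation p = 0.1). In the untrained libraries 1, 3 and 1 of the 14 macrophage markers had any count, so this sum rests on few genes and does not show macrophages. Tendon sums were 149.6 and 26.7 CPM, adipocyte sums 58.7 and 25.9 CPM and Schwann cell sums 0 and 5.53 CPM. In the untrained libraries 2, 3 and 4 of 9 tendon markers and 1, 3 and 1 of 8 adipocyte markers had any count.

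Immediate early genes were negative in 14 of 20 cases and not called as a list (camera adjusted p = 0.0662), with 2 lower adjusted over the list alone. Fos, a subunit of the AP-1 transcription factor (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273), averaged 1282 ± 1067 CPM in untrained and 136 ± 40.3 CPM in trained type IIb fibres (log2 fold change -3.24 ± 0.73 SE) and was not called over all genes. Adjusted over the list alone, 1 slow contractile gene was higher and 4 lower, and 1 gene each was higher in the tricarboxylic acid cycle list (Idh2, 28.9 and 111 CPM), the mural list and the erythroid list. Gpx3 averaged 67.4 and 297 CPM and Myh4 37327 ± 15907 and 63112 ± 37916 CPM. Ppargc1a averaged 42.5 and 45.1 CPM and Vegfa 159 and 137 CPM (adjusted p = 1 for each, edgeR). The 26 lists that were not called had camera adjusted p between 0.0662 and 0.861. In single leave-outs 8 of them were called: immediate early, slow contractile and ribosomal protein genes, heat shock, the circadian clock and endoplasmic reticulum stress lower, and mural markers and extracellular matrix higher (camera adjusted p = 0.00156 to 0.0482). Immediate early, mural and matrix genes were also called without the 2 libraries with the fewest genes (0.0402, 0.0353 and 0.0171), and ribosomal proteins, lower without type IIb untrained library 2 or type IIb trained library 1 (0.00156 and 0.00217), were called higher without the 3 marker libraries (0.0412).

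Whether training acted differently on the fibre types was tested as the difference between both training effects (type I minus type IIb). Lists of nuclear OXPHOS, ribosomal proteins, mitochondrially encoded genes and heat shock had more positive training effects in type I than in type IIb fibres, and endothelial, fibroblast and mural markers and extracellular matrix more negative ones. No list kept its call with an estimated correlation. Of 11747 genes, 0 were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (smallest adjusted p = 0.418), with 1050 at an unadjusted p under 0.05 (113 higher, 937 lower), while DESeq2 called 28 higher and 334 lower and limma-voom with quality weights 0. Across genes, which are not independent replicates, both training effects correlated with Pearson r = -0.198 and Spearman rho = -0.135.

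Nuclear OXPHOS genes had a median difference of 0.71 on the log2 scale (56 of 76 positive, camera adjusted p = 1.01e-11), with Cox7c at 2.00 ± 0.76 SE and Atp5j at 1.70 ± 0.61 SE (adjusted p = 0.450 and 0.424, edgeR). Ribosomal protein genes had a median of 0.63 (45 of 54 positive, camera adjusted p = 6.58e-08), mitochondrially encoded genes 0.99 (13 of 13, 0.00129) and heat shock genes 0.86 (14 of 16, 0.00325). Slow contractile genes were called in the positive direction (camera adjusted p = 0.00222) although 8 of 15 members were negative (median -0.30, mean 0.27), and 2 members passed adjusted over the list alone. These were Myl2 and Tnnc1, the slow troponin C, with differences of 4.46 ± 1.13 SE and 7.06 ± 1.75 SE (adjusted p = 0.418 for both, edgeR). Both came mostly from low levels in type IIb fibres, where Myl2 had 19 counts in untrained and 1 in trained libraries and Tnnc1 averaged 13.3 ± 16.9 and 0.0671 ± 0.0648 CPM. Tricarboxylic acid cycle genes (15 of 23 positive, median 0.09) and fatty acid genes (13 of 26 positive, median 0.017, mean -0.54) were called at camera adjusted p = 0.0280 and 0.0353. Idh2 had a difference of -1.73 ± 0.64 SE (adjusted p = 0.433, edgeR). Endothelial, fibroblast, extracellular matrix and mural lists were called in the negative direction (camera adjusted p = 8.87e-08, 4.35e-05, 0.00155 and 0.00295), with 12, 9, 9 and 4 members lower adjusted over the list alone. The 11 called lists had adjusted p between 0.466 and 0.801 with an estimated correlation. The other 18 lists had camera adjusted p between 0.0834 and 0.893. Without type IIb trained library 3 the endothelial, mural, matrix, heat shock, ribosomal, slow contractile and mitochondrially encoded lists were not called (camera adjusted p = 0.167, 0.898, 0.898, 0.263, 0.128, 0.0809 and 0.227), and the correlation of training effects was 0.015. The mitochondrially encoded list was also lost without type I trained library 2 (0.384), the heat shock list without type I trained library 1 (0.0638), the mural list without type I trained library 3 or type IIb untrained library 2 (0.179 and 0.232) and the matrix list without type I untrained library 3 or type IIb untrained library 2 (0.0739 and 0.255). The lists of fatty acid use and the tricarboxylic acid cycle were not called in 6 and 5 of the leave-outs (up to 0.476 and 0.246). Neither was called without the 2 libraries with the fewest genes. Without the 3 marker libraries the 1 list called was nuclear OXPHOS (median 0.45, camera adjusted p = 0.0364), with 0.84 for mitochondrially encoded genes, 0.67 for heat shock and -0.053 for ribosomal proteins. Of the lists that were not called, fast contractile genes were called lower without type I trained library 2 (0.0403) and interferon without type I untrained library 2 or type IIb trained library 2 (0.0135 and 0.0436) and without a filter (0.000361). Antioxidant defence was called higher without the 2 libraries with the fewest genes (0.0190).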

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

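A test chosen only after the result was seen was the share of markers held by 1 library. It was for cells of other types carried over into single libraries. The fit without the 3 libraries with the highest endothelial markers was also chosen then.

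The difference between both training effects was tested for every gene list, and 11 lists differed at the preset correlation. These were nuclear OXPHOS (camera adjusted p = 1.01e-11), ribosomal proteins (6.58e-08), mitochondrially encoded genes (0.00129), slow contractile genes (0.00222, with 7 of 15 members positive), heat shock (0.00325), the tricarboxylic acid cycle (0.0280) and fatty acid use (0.0353) in the positive direction, and endothelial markers (8.87e-08), fibroblast markers (4.35e-05), extracellular matrix (0.00155) and mural markers (0.00295) in the negative direction. Each had an adjusted p of 0.466 or more with an estimated correlation. These directions are relative to other genes, and the median difference of all genes was -0.68. A list in the positive direction therefore need not have mostly positive members. Of 100 splits of the training labels within fibre types, 6 gave 11 lists or more, the real one included, and the highest of the other splits gave 12, so chance is not excluded for this number of lists. The median of the other splits was 6 lists. For genes, 100 of 100 splits gave as many as the real 0, and the highest other gave 2.

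The first pattern weighed is that endothelial and fibroblast markers were lower with training in type I and higher with training in type IIb fibres, with matrix genes lower in type I and called in the interaction. The number of genes detected per library, if it acts by level and length alone, would move lists of like level and length as far. The endothelial list lay at percentile 0 of 1000 such lists in the interaction, which argues against it in that form. Cells of other types carried over into single libraries stay open as a candidate explanation. In this case the level would rest on 1 or 2 libraries of a group, and the highest library held 64.7% of the summed endothelial markers in untrained type I and 99.6% (290.7 CPM, with 1.06 CPM in both others) in trained type IIb fibres, a weak test since capillaries that differ between single fibres may give the same shares. Without the 3 marker libraries no vascular or matrix list was called for training or the interaction, which is built into how those libraries were picked. Those libraries also had the most genes detected in their groups, so this fit cannot separate carried-over cells from the number of genes detected. A biological change of vessels and matrix with training stays open and untested.

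The second pattern weighed is that nuclear OXPHOS and ribosomal protein genes were higher in trained type I fibres. For the number of genes detected per library, 1000 lists matched on level and length were predicted to move as far as OXPHOS. They did: the OXPHOS median of 0.45 lay at percentile 71.0 of these (middle 95% from 0.26 to 0.58). The number of genes detected did not enter the matching, so this cannot tell it from other causes that act by level or length. For gene length or expression level of ribosomal protein genes, the ribosomal median of 0.68 lay at percentile 99.8 (middle 95% from 0.20 to 0.58). The median of the matched lists was 0.37, so level and length can give part of this rise. Matched genes were drawn at random, so their range may be too narrow for genes that move together. In the interaction the order was the opposite, with OXPHOS at percentile 98.1 and ribosomal proteins at 75.3. There the OXPHOS median of 0.71 lay outside the middle 95% of the matched lists (0.23 to 0.69). Whether a cause acting by level and length alone gives the ribosomal part in type I, or the OXPHOS part in the interaction, stays open. Neither list kept its call with an estimated correlation (adjusted p = 0.519), and an effect of training on either group of genes stays open.

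For the other comparisons, 3 libraries against 3 make 10 splits, too few for a share under 0.05. Of these splits, 10 gave as many genes as the real 0 with training in type I (highest other 0) and 10 as many as the real 0 with training in type IIb (highest other 7). Between fibre types 1 split, the real one, gave 54 genes in untrained mice and 1 gave 63 in trained mice (highest other 0 in both). For lists, 2 splits gave at least the real 13 with training in type I (highest other 13), 9 splits at least the real 3 with training in type IIb (highest other 7), 1 split the real 17 in untrained mice (highest other 16) and 2 splits at least the real 10 in trained mice (highest other 11). The median of the other splits was 10 lists with training in type I, 4 with training in type IIb, 10 in untrained and 7 in trained mice. Wrong groupings of these libraries thus called many lists at the preset correlation, and more than the real one with training in type IIb.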

How the results depend on the processing

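Leaving out the 3 libraries with the highest endothelial markers was a test chosen only after the data were seen. The same holds for leaving out the 2 libraries with the fewest genes. The other alternatives were planned, all could be run, and unless a cause is named below the cause was not tested. All 54 and 63 genes called between fibre types kept their sign in every alternative, and DESeq2 shared 42 and 50 of these calls, limma-voom 38 and 36 and the fit with only the 2 groups compared 40 and 36. The stricter filter and the added fold threshold changed the side of the threshold of none of the 159 gene results. With 3 libraries a group, simulated 4-fold changes were mostly missed, so a gene that was not called may still have changed, as the 1028 and 53 genes DESeq2 called in untrained mice against 30 and 24 leave open. Differences in genes detected with training kept their sign at 1 count, at 1 CPM and after thinning to the smallest total, with -2330, -3347.3 and -3296.3 in type I and 2200.3, 782 and 774.3 in type IIb.

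DESeq2's Wald test called 1 higher and 46 lower with training in type I, 277 and 46 with training in type IIb, 1028 and 53 between fibre types in untrained mice, 171 and 113 in trained mice and 28 and 334 in the interaction. It gave a p-value for 25809 genes, but more genes alone do not account for these calls. EdgeR without a filter tested 28696 genes and called 123 in untrained mice, against 1081 with DESeq2. Limma-voom with quality weights called 1 and 3 with training in type I, 1 higher with training in type IIb, 1868 and 238 between fibre types in untrained mice and 126 higher in trained mice. No filter on low counts gave 7 lower with training in type I, 6 higher and 3 lower with training in type IIb, 93 higher and 45 higher between fibre types in untrained and trained mice, 4 higher and 22 lower in the interaction and 3 lists up with training in type I. Limma on log2(FPKM + 1) called 292 higher and 37 lower in untrained and 88 higher in trained mice, and on log2(FPKM + 0.1) 275 and 81 higher. EdgeR without a robust prior called 14 lower in untrained mice, and the fit of only the groups compared 18 lower in trained mice, with fewer samples. An estimated correlation left 0 lists called up or down for training in either fibre type and the interaction, and 1 up and 1 down in each comparison of fibre types. Fry called 0 lists up or down for training and the interaction, 6 up and 2 down in untrained mice and 2 up and 2 down in trained mice. Among the 6 were immediate early genes and heat shock (fry adjusted p = 0.00832 and 0.0177), which camera did not call (0.0851 and 0.156), and fry does not compare a list with other genes. It also turned the direction of the tricarboxylic acid cycle list in untrained mice (adjusted p = 0.663, against 0.0312 to 0.626 with camera).

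Uncalled genes also turned direction. The log2 fold change of Ppargc1a with training in type I (0.011) was -0.22 with RLE, -0.23 with DESeq2, -0.038 without a filter, -0.30 and -0.33 on log2(FPKM + 1) and log2(FPKM + 0.1) and -0.32 without the 3 marker libraries. Limma-voom turned Hspb6 with training in type I to -0.42, and Myh1 to 3.87 with training in type IIb and 2.96 between fibre types in untrained mice. Myh1 with training in type IIb was 0.011 and 0.78 on log2(FPKM + 1) and log2(FPKM + 0.1), and on log2(FPKM + 1) the interaction was -0.24 for Myh4 and 0.11 for Myh7.

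With the replicate block, which uses the replicate number as a term in the fit, 16 genes were higher in type I fibres of trained mice (28 without it), and the correlation of training effects was -0.05 (-0.198 without it). Ppargc1a with training in type I was -0.34 and Myh1 with training in type IIb 1.80. The fit with the block shared 40 of the 54 calls between fibre types in untrained and 41 of the 63 in trained mice. Among the genes chosen by the naming rule and the lists called without it, the block ended the calls of Mstn (adjusted p = 0.0635 and 0.0564 in untrained and trained mice), Ppp1r3a (0.0703), Prkab2 (0.0874), Vgll2 (0.0983) and Tbx15 (0.131), and of the lists of branched-chain amino acid breakdown and interferon with training in type I (0.0682 and 0.0954) and of erythroid markers in trained mice (0.0825), and of no others, and it added the tendon list with training in type I (0.0461). The numbers were not taken as pairs, since 4 of 18 pairs with the same number correlated above 0.1 (-0.121 to 0.199) and 6 of 12 libraries correlated best with their own number.

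Without the 3 marker libraries, which leaves fewer samples and 1 untrained type I library that is assumed to vary like the other groups, 18 genes were higher and 7 lower between fibre types in untrained mice and 2 were lower with training in type IIb. Lists called were 0 up and 0 down with training in type I, 1 up with training in type IIb (ribosomal proteins), 4 up in untrained mice and 1 up and 0 down in the interaction, and the correlation of training effects was 0.03. OXPHOS was still called lower with training in type IIb. Directions turned for the extracellular matrix, fibroblast and slow contractile lists with training in type I (adjusted p = 0.542, 0.974 and 0.974) and the ribosomal and extracellular matrix lists in the interaction (0.459 and 0.596). The slow contractile list also turned without a filter (0.905). Smoc2, Myh1 and Ppargc1a turned to 2.00, 0.95 and -0.32 with training in type I, Myh1 and Ppargc1a to 0.24 and -0.61 with training in type IIb, and Fn1, Myh7, Myh1, Vegfa and Ppargc1a to 0.49, 0.32, 0.72, 0.25 and 0.29 in the interaction. Without the 2 libraries with the fewest genes, 1 gene was lower with training in type IIb, 1 was higher in the interaction, and 4 lists were up and 2 down with training in type IIb. This choice ended 6 list calls. In trained mice they were mitochondrially encoded genes, glucose uptake, fibre type regulators and erythroid markers, and in the interaction the tricarboxylic acid cycle and fatty acid use. Myh1 and Ppargc1a turned to 0.42 and -0.13 in untrained mice, and Ppargc1a to -0.11 in trained mice and 0.026 in the interaction.

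Leaving out each library in turn gave 0 to 1 lower genes with training in type I, 0 to 2 lower with training in type IIb and 0 to 2 higher in the interaction. Between fibre types it gave 14 to 39 higher and 8 to 30 lower in untrained and 13 to 40 higher and 16 to 37 lower in trained mice. Lists called ranged from 4 to 9 up and 0 to 7 down with training in type I, 0 to 4 up and 0 to 6 down with training in type IIb, 3 to 10 up in untrained mice, 3 to 7 up and 3 to 7 down in trained mice, and 2 to 7 up and 1 to 5 down in the interaction. The correlation of training effects ranged from -0.186 to 0.015, and the difference in genes detected with training in type IIb from -1168.8 to 2225.3, with -541.7 without type IIb untrained library 1. Myh1 ranged from -6.35 to 1.45 with training in type I, -2.06 to 1.65 with training in type IIb, -4.46 to 0.43 in untrained mice and -6.21 to 1.58 in the interaction. Myh7 ranged from -0.020 to 1.31 with training in type I and -2.29 to 0.86 in the interaction. Ppargc1a ranged from -0.28 to 0.26 and -0.56 to 1.12 with training in type I and type IIb, -0.10 to 1.52 and -0.14 to 1.03 in untrained and trained mice and -1.11 to 0.65 in the interaction. Vegfa ranged from -0.38 to 0.043 with training in type IIb, -0.077 to 0.63 in trained mice and -0.63 to 0.12 in the interaction. Adjusted p of the fast contractile list ranged from 0.0429 to 0.967 and 0.175 to 0.968 with training in type I and type IIb and 0.0403 to 0.974 in the interaction, and of the immediate early list in the interaction from 0.503 to 0.998, and these turned direction in 3, 1, 2 and 3 of the leave-outs. Of the results of single genes in these leave-outs, 1807 kept side and direction, 60 lost a call, 14 gained one and 27 turned direction.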

Other observations

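The tests of exons shared with another annotated gene and of the yield of contractile transcripts, the bound for reads shared with Myh6, and the genes named in the next paragraphs, were chosen only after the values were seen.

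Further genes that differed between fibre types in both untrained and trained mice were found among the calls of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Ldhb, the lactate dehydrogenase subunit of oxidative muscle and heart, averaged 1819 and 3083 CPM in untrained and trained type I fibres and 0.451 and 5.70 CPM in type IIb fibres (adjusted p = 0.0186 and 0.0430). Actc1, the cardiac form of sarcomeric actin, was lower in type I fibres, with 59.6 and 19.5 CPM against 2069.5 and 380.1 CPM (adjusted p = 0.0186 and 0.0430). Myl12a, a light chain of nonmuscle myosin, averaged 1066 and 1168 CPM in type I and 137 and 88.3 CPM in type IIb fibres (adjusted p = 0.00422 and 0.000359). Pdlim1, a PDZ and LIM domain protein of the cytoskeleton, averaged 448 and 417 CPM in type I and 0 and 1.73 CPM in type IIb fibres (adjusted p = 0.00173 and 0.0261). Dkk2, a secreted Wnt regulator, averaged 98.0 and 69.1 CPM in type I fibres and had no counts in type IIb fibres (adjusted p = 0.02497 and 0.0302). Lower in type I fibres were Phkb, a subunit of the kinase that activates glycogen breakdown (65.1 and 69.6 CPM against 465 and 535 CPM, adjusted p = 0.0290 and 0.0210), and Ddit4l, an inhibitor of growth signalling (58.0 and 51.2 CPM against 585 and 640.4 CPM, adjusted p = 0.0176 and 0.00708). Ckm, the muscle creatine kinase, averaged 170 and 166 CPM in type I against 649 and 1463 CPM in type IIb fibres, and passed in trained mice alone (adjusted p = 0.0151, and 0.230 in untrained mice), while the interaction, which tests the difference, had adjusted p = 0.796.

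Of genes in lists that were not called, Esrrb and Esrrg, nuclear receptors of oxidative metabolism, averaged 36.1 ± 8.68 and 82.2 ± 1.65 CPM (SD, n = 3) in untrained type I fibres and 0 and 1.29 ± 2.23 CPM in untrained type IIb fibres (edgeR adjusted p = 0.113 and 0.230, not called). Cat, the catalase gene, averaged 270.3 ± 32.2 and 587 ± 353 CPM in untrained and trained type I fibres and 51.6 ± 47.7 and 46.6 ± 56.6 CPM in type IIb fibres. Ache, the esterase of the neuromuscular junction, averaged 2.76 ± 2.77 and 0.0297 ± 0.0514 CPM in type I and 10.0 ± 13.7 and 16.3 ± 14.4 CPM in type IIb fibres.

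The third pattern weighed is that transcripts central to a fibre type had few counts, Tnnc2 in type IIb fibres (0.0844 CPM in untrained fibres) and Myh7 in type I fibres (387 CPM). A low yield of all contractile transcripts is argued against by the median of 2786 CPM over the other contractile genes in their own fibre type. For Tnnc2, loss of reads in counting may contribute, because 74.0% of its exon bases are exons of another annotated gene (Ube2c, on the other strand), against a median of 0 over 29 other contractile genes. A loss in proportion to this share falls short of the low level, since Tnni2 and Tnnt3 of the same list averaged 21790 and 24260 CPM in type IIb fibres. Whether counting lost more reads than this share was not tested. For Myh7, exons shared with Mhrt and other genes (13.3% of its exon bases) and reads shared with its paralog Myh6 (11.2% of its 100-base words, against 3.85% for Myh4) are both too few to take most of its reads, where the bounds were set after these shares were known. What keeps Myh7 low stays open, and no biological explanation was tested.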
